A study of Xenopus tropicalis with 4 samples.

How the data were processed

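The measurement was chromatin immunoprecipitation followed by sequencing, in which DNA fragments attached to a protein are pulled down with an antibody and counted along the genome. The 4 samples were whole Xenopus tropicalis embryos at stage 8, a blastula stage. Per the labels, 2 samples came from embryos injected with E2F1 mRNA and an MO and were precipitated with an HA antibody, and 2 came from embryos injected with OTX1 mRNA and an MO and were precipitated with a Myc-tag antibody. MO is the usual short form of morpholino oligonucleotide in this field, and the labels do not spell out its target. Chromatin was prepared with a sonication kit and libraries with a commercial DNA kit, per the labels' protocols. Each sample came with its own list of called peaks, so replicates could be compared as separate lists. Nothing in the labels says that the replicates were separate batches of embryos, and the peak names of the OTX1 lists speak of library replicates, so the spread between replicates may be technical.

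The submitters' processing notes name fastp, Bowtie2 2.4.5, MACS2 2.2.7.1 and deepTools without a role or an order for any of them. Input or control libraries were not analysed here, and whether the peak caller used any is not given in the sources used here. The deposited lists give a score per peak, which equalled the whole part of 10 times the −log10 of the q-value in 100% of the peaks of each list. The authors' fold per peak is the ratio of the signal at the summit to the peak caller's local background within that library. If no control was used, that background includes the immunoprecipitated signal itself, which would lower the fold of broad or tall signal. The deposited lists also hold the −log10 of the p-value and of the q-value at the summit, and the offset of the summit from the peak start. These values are the authors' own and served only to describe, rank or filter peaks within a list. The least significant peaks had a q of 0.0492 and 0.0470 in the E2F1 lists and 0.00999 and 0.00977 in the OTX1 lists, so the peaks of the factors were called at different thresholds.

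Read totals are not in the lists. The fold and the p of each peak were solved together for the whole number of fragments at the summit and the local background, taking the fold as (pileup + 1) / (background + 1) and the p as the upper tail of a Poisson distribution. A whole pileup was found for 100% of the peaks of each list with a misfit in −log10 p of at most 4.56e-05, while the next whole number missed by at least 0.0950. The median summit pileup was 16 and 16 fragments in the E2F1 lists and 16 and 15 in the OTX1 lists. The lowest background was 1.13, 1.25, 1.59 and 1.35 fragments in the same order. It depends on fragment length as well as depth, so it does not rank the depth of the factors' libraries. The smallest peak width was 268 and 258 bp for E2F1 and 160 and 147 bp for OTX1. Peak widths are therefore not directly comparable between the factors. Pileups of this size carry a counting error of several fragments, so the order of weak peaks is uncertain. Fragments are not independent molecules where amplification copied them. The intervals of odds ratios below come from counts of genes or regions and cover neither this error nor the spread between replicates.

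The peak names of the OTX1 lists carry the build name xenTr10, and the E2F1 lists use the same sequence names. Gene positions came from a RefSeq gene table for the assembly UCB_Xtro_10.0, which matched the lists: 39.9% and 36.4% of E2F1 summits and 6.43% and 5.57% of OTX1 summits lay within 500 bp of an annotated gene end, against 2.84% to 3.86% after every summit was moved by 5, 20 or 100 kb to either side. Coordinates are 1-based on xenTr10. The gene table gives the start and end of each gene without strand, transcripts, exons or UTRs. The promoter of the planned tests, the 5′ end of a gene, was therefore replaced by either annotated end of a protein-coding gene, and a region is called at a gene end when its summit lies within 1 kb of one. Among 3317 genes of at least 10 kb that lay at least 20 kb from their neighbours and had an E2F1 region at an end, 99.2% had it at 1 end alone. Of 21749 protein-coding genes on the 10 chromosomes, 6157 have only a locus number as a symbol and are not named. No genome sequence was used, so the planned tests for E2F and OTX motifs and the planned matching on GC content were not run.

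Peaks of both lists of a factor that shared at least 1 bp were joined into reproducible regions, with the summit of the peak of higher fold percentile in its list. Regions of the factors were shared when they overlapped by at least 1 bp. Regions called E2F1-only or OTX1-only overlapped no peak of either list of the other factor. Chance overlap came from 1000 seeded placements of the regions at random positions of the same sequence, with a one-sided permutation p whose smallest value is 0.001. Placements were also drawn with gene-end regions kept at gene ends. Shares of genes were compared with two-sided Fisher's exact tests, with 95% intervals of the odds ratio by Woolf's method with a continuity correction, and Benjamini-Hochberg adjustment over 12 gene lists and both factors (24 tests). Genes and regions are not replicates, so these p-values describe the lists, not repeated experiments. Libraries were compared by an exact permutation test, which with 2 against 2 cannot give a two-sided p below 0.333. Random lists matched on gene length (10 classes) and spacing (5 classes) were drawn 10000 times.

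Before the data were examined, the gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists were DNA replication, cell cycle and the E2F-RB network, endoderm and mesendoderm, organizer and axis, ectoderm and neural plate, maternal transcription factors, core transcription machinery, ribosomal proteins, histones, signalling ligands and receptors, hox genes and late differentiation genes. Named genes were the 10 with the highest mean fold percentile within the lists in each of 3 classes of regions (E2F1-only, OTX1-only, in all 4 lists), up to 4 per gene list and factor in the same order, and a fixed set (e2f1, otx1, otx2, pou5f3 genes, sox3, nodal genes, sia1, sia2, gsc, mix1, pcna, mcm genes, ccne1, cdc25a and chek1). Some genes that met this rule are not reported here. Alternatives were other overlap rules, stricter thresholds, equal list sizes, chromosomes alone, other windows and single replicates, and after the data were examined also a common threshold, gene bodies, matched lists and the removal of peaks whose local background exceeded 3 times the lowest of their list. Overlap, gene-list and pileup steps were tested on simulated data: planted overlaps of 80%, 60% and 0% came back as 80.1%, 60.3% and 1.44%, and of 100 simulated lists of 60 genes, 98 were called when 60% of the genes had a region and 7 when 35% had, the share among all genes. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.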

Results

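E2F1 and OTX1 are transcription factors that frog eggs carry as maternal products, and the series asked how they act together on the earliest zygotic genes. Binding was mapped in Xenopus tropicalis embryos at stage 8 with tagged versions of each factor, in 2 libraries per factor. The E2F1 lists held 16770 and 20385 peaks with median widths of 426 and 413 bp. The OTX1 lists held 27755 and 29098 peaks with median widths of 276 and 259 bp. The summits rested on a median of 16 and 16 fragments in the E2F1 lists and 16 and 15 in the OTX1 lists.

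The replicate lists of each factor overlapped far more than chance, although many regions were in 1 list alone. Of the E2F1 peaks, 79.4% of replicate 1 and 65.2% of replicate 2 overlapped a peak of the other list, which gave 13216 reproducible regions, 55.6% of the 23751 regions in either list. Of the OTX1 peaks, 64.5% and 61.9% overlapped, which gave 17768 reproducible regions, 45.9% of 38711. Random placement of replicate 1 matched 1.40% of E2F1 peaks and 1.23% of OTX1 peaks, and no placement reached the observed number (permutation p = 0.001 for both, the smallest that 1000 placements can give). Across reproducible regions, which are not independent replicates, the fold of the lists had a Spearman correlation of 0.735 for E2F1 and 0.612 for OTX1. With equal numbers of top peaks in every list, the OTX1 count was 10902.

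E2F1 was concentrated at the ends of genes. Of its 13216 regions, 6798 (51.4%) had their summit within 1 kb of an annotated end of a protein-coding gene, 9.10 times the 5.65% of randomly placed regions (permutation p = 0.001, the smallest possible). A further 24.4% lay inside genes farther from their ends. In the separate lists the share at gene ends was 42.8% ± 2.51 (SD, n = 2). In all, 7596 of 21749 protein-coding genes (34.9%) carried an E2F1 region at an end, and 11642 had a region inside the gene or within 10 kb.

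Genes for DNA replication carried E2F1 almost as a whole. Of the 64 members of that list, 59 (92.2%) had an E2F1 region at an end, against 34.8% of other genes (odds ratio 22.2, 95% interval 8.47 to 48.7, Fisher's exact adjusted p = 2.17e-20). The member with the highest fold percentile was cdc6, which loads the replicative helicase onto origins, with a fold of 17.0 and 19.8 in replicates 1 and 2 (chromosome 10, 8871248 to 8872065). Next came rrm1, the large subunit of ribonucleotide reductase, with 17.5 and 16.6 (chromosome 2, 178118761 to 178119501). Behind them were dnmt1, the maintenance DNA methyltransferase, with 15 and 17.7, and mcm6.2, a subunit of the helicase, with 14.8 and 17.9. Of the other mcm genes, mcm2 (11.0 and 11.5), mcm4 (11.9 and 12.2), mcm5 (11.4 and 10.5), mcm7 (8.78 and 9.73), mcm8 (10.2 and 13.9), mcm9 (5.25 and 5.35) and mcm10 (8.09 and 8.32) also carried one. The region at mcm3 had its summit 1270 bp from the gene's end, and mcm6 had no reproducible region within 10 kb. The gene of the sliding clamp, pcna, had a region 51 bp from its end with folds of 8.71 and 10.3.

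The genes of the cell cycle and of the E2F-RB network carried E2F1 at an end in 58 of 72 cases (80.6%, odds ratio 7.77, 4.26 to 13.5, exact adjusted p = 1.43e-14). E2f1 itself had an E2F1 region over its end (chromosome 10, 41691216 to 41692108, summit 28 bp from the end) with folds of 10 and 12.7. The leading members were e2f8, an atypical E2F (14.2 and 15.5), the cyclin-dependent kinase subunit cks1b (13.4 and 15.1), the topoisomerase top2a (13.2 and 14.0) and rbl1, a relative of the retinoblastoma gene (13.5 and 13.5). The regulators of the division rhythm cdc25a (13.3 and 12.1), chek1 (8.56 and 8.23) and ccne1 (6.12 and 8.57) carried it too.

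E2F1 also marked the genes of basic gene expression. In the core transcription machinery, 70 of 89 genes (78.7%) had a region at an end (odds ratio 6.92, 4.11 to 11.2, exact adjusted p = 6.76e-16), led by gtf2h1, a subunit of the factor TFIIH (13.8 and 16.1), and by taf6 (14.4 and 14.5) and taf13 (13.6 and 15.2), subunits of TFIID. Of the genes for ribosomal proteins, 62 of 78 (79.5%) did (odds ratio 7.27, 4.13 to 12.2, exact adjusted p = 6.89e-15), led by rps13 (13.4 and 15.8) and rpl13a (11.8 and 13.0). Of the maternal transcription factors, 21 of 38 (55.3%) did (odds ratio 2.31, 1.22 to 4.31, exact adjusted p = 0.0279), among them tead1 (13.1 and 14.8), mycn (11.0 and 12.9), nfyc (11.0 and 12.7) and yy1 (11.1 and 12.3). The highest E2F1-only regions at gene ends lay at znf250 (20.3 and 22.8), tonsl, which acts at replication forks (19 and 22.5), srrt (18.9 and 23.9) and the RNA-editing enzyme adar (18.2 and 22.7). Next were csnk2a1, a kinase subunit (18.2 and 20.6), and the nuclear import factor ipo7 (19 and 19.3). They were followed by the shared end of gon4l and syt11 (17.7 and 19.8), naa50 (17.9 and 19.4) and mpdu1 (18.0 and 19).

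Late differentiation genes were largely free of E2F1. Only 9 of 137 (6.57%) had a region at an end (odds ratio 0.130, 0.0707 to 0.264, exact adjusted p = 3.41e-14), with cryba1.2 (8.47 and 9.58), mbp (8.23 and 8.66), nefl (5.69 and 8.26) and tnnt3 (5.98 and 6.34) as those with the highest folds. The list takes in genes of the crygdl family, of which 1 of 37 had E2F1 at an end, so its members are not all independent. The other lists did not pass the test at gene ends, which does not show that they equal other genes. Histones had 13 of 28 genes, including h2bc14 (exact adjusted p = 0.281), ectoderm 19 of 43, including krt8.1 and gmnn (0.272), and signalling 42 of 98, including notch1 and efna3 (0.205). Against random lists matched on gene length and spacing, histones (permutation adjusted p = 0.0096) and ectoderm (0.0380) did pass. Organizer and axis genes had 10 of 35, including tsku and szl (exact adjusted p = 0.526), endoderm and mesendoderm 12 of 48, including fgf20 and lefty (0.255), and hox 7 of 36, including hoxc10 (0.119). Without peaks in a high local background, a setting chosen after the data were examined, the DNA replication list still passed, but with an odds ratio of 2.67 (exact adjusted p = 0.000782), and cdc6, rrm1, dnmt1, pcna, mcm2, mcm4, mcm5, mcm6.2, mcm7 and mcm10 lost their E2F1 regions. The cell cycle list no longer passed (odds ratio 1.81, exact adjusted p = 0.0687), with e2f1, e2f8, cks1b, top2a, rbl1, cdc25a and ccne1 among the losses. The maternal list turned to an odds ratio of 0.354 (exact adjusted p = 0.0852), with mycn, nfyc and yy1 among its losses. Core transcription (odds ratio 4.47) and ribosomal proteins (3.54) still passed, and hox genes came out below other genes (0.0860, exact adjusted p = 0.00351). This filter took out tall peaks. In the E2F1 lists the removed peaks had a median summit pileup of 35 and 41, against 14 and 15 for the others. A region lost under the filter is therefore not shown to be background. The maternal list also missed the threshold with a reciprocal overlap of 50% (exact adjusted p = 0.122) and with a window of 500 bp (0.117).

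**Figure D1:**
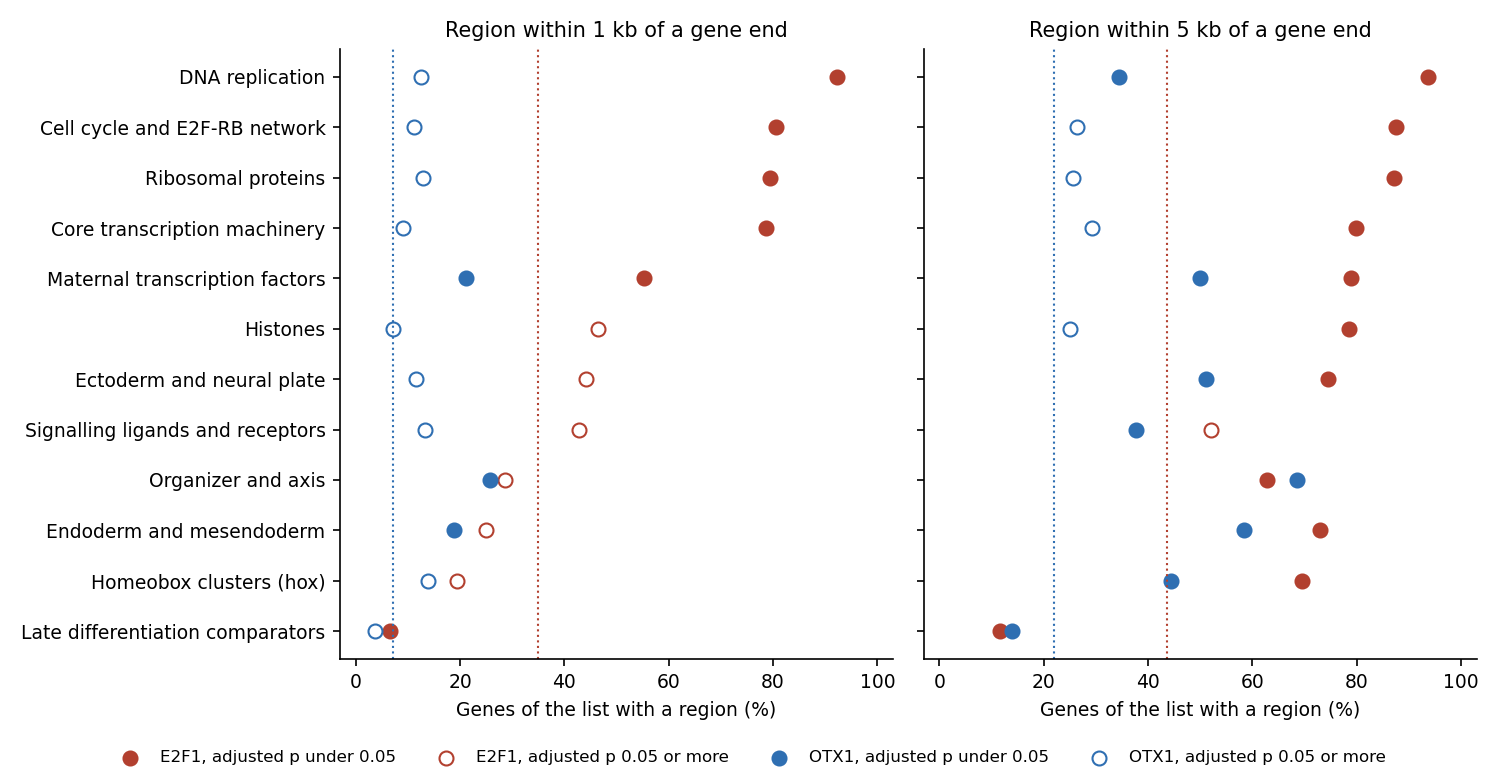
Percent of the genes of each list (vertical axis) that had a region of E2F1 (red) or OTX1 (blue) within 1 kb (left) or 5 kb (right) of a gene end, with filled points for a Fisher's exact adjusted p under 0.05 and dotted lines for other genes. At 1 kb, E2F1 reached 92.2% of the DNA replication genes and OTX1 25.7% of the organizer and axis genes.

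OTX1 lay mostly away from gene ends. Of its 17768 regions, 1479 (8.32%) had their summit within 1 kb of a gene end, 1.49 times the 5.58% of randomly placed regions (permutation p = 0.001, the smallest possible). Inside genes lay 47.0% of the regions, and 30.2% lay outside genes and more than 10 kb from any gene end. In the separate lists the share at gene ends was 9.11% ± 0.697 (SD, n = 2), below both E2F1 lists. The difference of 33.7 percentage points between the factors had an exact permutation p = 0.333, the smallest that 2 against 2 libraries allow, and the antibody and the calling threshold differed between the factors as well. Across reproducible regions the odds of lying at a gene end were 11.7 times higher for E2F1 than for OTX1 (95% interval 10.9 to 12.4).

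**Figure D2:**
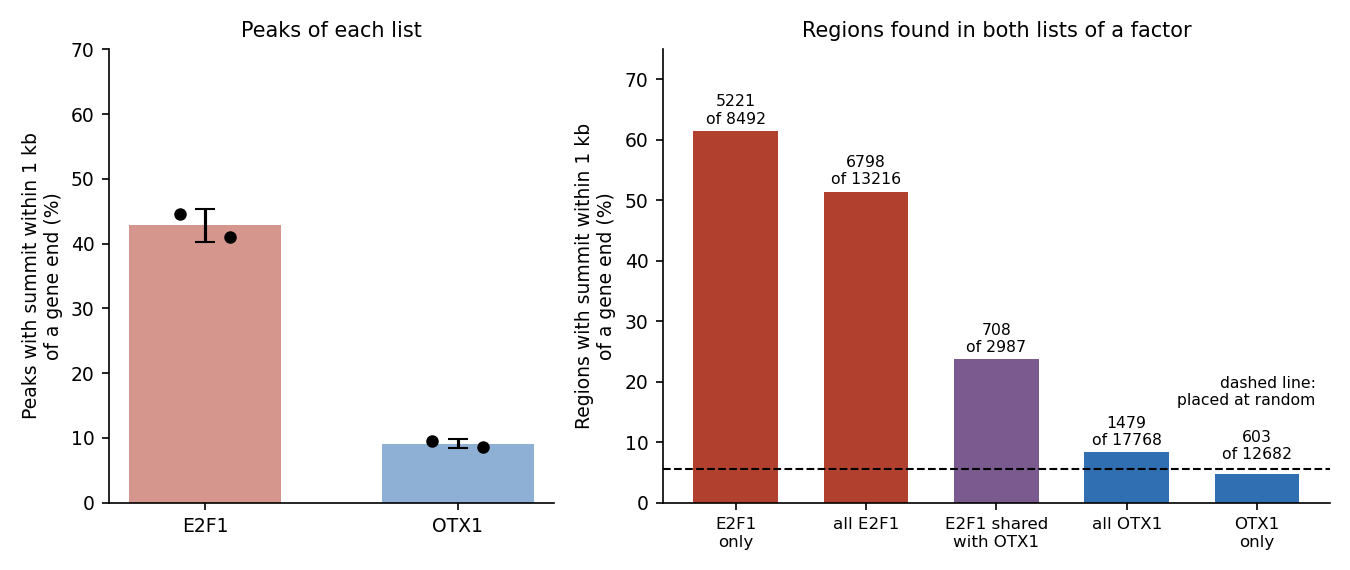
Left, percent of the peaks of each list with the summit within 1 kb of a gene end; bars are means, points the 2 lists, error bars SD; right, the same percent for reproducible regions by class, with a dashed line for random placement. E2F1-only regions were at gene ends in 61.5% and OTX1-only regions in 4.75%.

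OTX1 was found at the ends of 1561 genes (7.18%), and the lists of organizer and axis, endoderm and mesendoderm and maternal factor genes were over-represented among them. Of the organizer and axis genes, which include ventral genes, 9 of 35 (25.7%) had an OTX1 region at an end against 7.15% of other genes (odds ratio 4.50, 95% interval 2.21 to 9.79, Fisher's exact adjusted p = 0.00253). The leading members were gsc, the homeobox gene of the organizer (folds of 5.69 and 7.76; chromosome 8, 88449163 to 88449838, summit 227 bp from the end), the ventral homeobox genes ventx3.1 (6.31 and 6.43) and ventx2.2 (5.94 and 5.87), and smad7, an inhibitor of TGF-beta signalling (4.75 and 7.16). Of the endoderm and mesendoderm genes, 9 of 48 (18.8%) did (odds ratio 3.0, 1.53 to 6.35, exact adjusted p = 0.0194), led by the homeobox genes mix1 (10.1 and 10.5) and mixer (8.65 and 14.3), with fgf20 (5.91 and 7.44) and sebox (5.2 and 6.80). Of the maternal transcription factors, 8 of 38 (21.1%) did (odds ratio 3.46, 1.69 to 7.75, exact adjusted p = 0.0167), led by the Y-box genes ybx1 (7.89 and 8.64) and ybx2 (4.25 and 5.95), with kdm5b (4.47 and 5.10).

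Apart from the maternal factors, the lists that E2F1 favoured did not pass the test for OTX1 with reproducible regions. The counts were 8 of 64 for DNA replication, including mcm10 and orc5 (exact adjusted p = 0.219), and 8 of 72 for the cell cycle, including cdca7 and rbl1 (0.281). Core transcription had 8 of 89, including cdk9 and taf11 (exact adjusted p = 0.556), and ribosomal proteins had 10 of 78, including rpl9 (0.145). In single OTX1 lists some of these did pass. Ribosomal proteins passed in replicate 1 (odds ratio 2.25, exact adjusted p = 0.0207) and in replicate 2 (2.25, 0.0129). Cell cycle (1.99, 0.0426) and core transcription genes (1.89, 0.0426) passed in replicate 1. Signalling genes had 13 of 98, including fzd8 and wnt5b (0.0686), ectoderm 5 of 43, including hesx1 and msx1 (0.281), and hox 5 of 36, including hoxd9 and hoxb6 (0.255). Histones had 2 of 28, h3c13 and h2afx.2 (exact adjusted p = 1), and late differentiation 5 of 137, including ttr and myh3 (0.219). Among OTX1-only regions, those at gene ends with the highest fold percentile lay at fucolectin, a lectin gene (12.0 and 12.3), the immunophilin fkbp4 (11.5 and 10.3), obsl1 (9.13 and 12.9), and prr29 (9.33 and 11.2). Next were erlin1 (10.4 and 10.2), the phosphatase methylesterase ppme1 (8.79 and 10.9) and the muscle gene myom3 (8.95 and 9.84). Below them came fam3d (10.3 and 9.14), the transporter slc37a3 (10.4 and 8.70) and dpm3 (9.22 and 8.92). Of these genes, fkbp4, ppme1 and dpm3 also had a separate E2F1 region at an end.

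The number of genes with OTX1 at an end ran from 829 with lists of equal size, 954 at a −log10 q of at least 5 and 1027 with summits within 100 bp to 2735 and 2563 in replicates 1 and 2 alone and 4791 in a 5 kb window. Without peaks in a high local background the organizer and axis (exact adjusted p = 0.411), endoderm (0.374) and maternal (0.423) lists no longer passed. Gsc, ventx3.1 and ventx2.2 lost their OTX1 regions. The removed OTX1 peaks were tall, with a median summit pileup of 29 and 28 against 16 and 15 for the others. Background and pileup had a Spearman correlation of 0.710 and 0.661 in these lists. Such losses therefore do not show that the regions are background. The maternal list also missed under 4 other alternatives, with an exact adjusted p of up to 0.537 (summits within 100 bp), and the endoderm list missed in replicate 2 alone (0.276), with summits within 100 bp (0.0741) and at a −log10 q of at least 5 (0.0537).

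Within 5 kb of gene ends, the organizer and axis, endoderm, ectoderm, maternal and hox lists had regions of each factor more often than other genes, and signalling genes had those of OTX1 but did not pass for E2F1 (51 of 98, odds ratio 1.40, exact adjusted p = 0.123). OTX1 lay there at 24 of 35 organizer and axis genes (68.6%, odds ratio 7.76, exact adjusted p = 2.03e-08), 28 of 48 endoderm and mesendoderm genes (58.3%, 4.98, 1.89e-07) and 22 of 43 ectoderm genes (51.2%, 3.72, 6.93e-05). It also lay at 19 of 38 maternal factors (50%, odds ratio 3.55, exact adjusted p = 0.000396), 16 of 36 hox genes (44.4%, 2.84, 0.00552) and 37 of 98 signalling genes (37.8%, 2.16, 0.000891). E2F1 lay there at 35 of 48 endoderm and mesendoderm genes (72.9%, odds ratio 3.49, exact adjusted p = 0.00013), 32 of 43 ectoderm genes (74.4%, 3.77, 0.000158) and 30 of 38 maternal factors (78.9%, 4.86, 3.27e-05). Also above other genes for E2F1 were 22 of 28 histone genes (78.6%, odds ratio 4.75, exact adjusted p = 0.000396), 25 of 36 hox genes (69.4%, 2.94, 0.00344) and 22 of 35 organizer and axis genes (62.9%, 2.19, 0.0328). Late differentiation genes were below other genes for both, with 16 of 137 for E2F1 (odds ratio 0.170, exact adjusted p = 6.55e-15) and 19 of 137 for OTX1 (0.568, 0.0302). DNA replication genes passed for OTX1 as well at this distance (22 of 64, odds ratio 1.86, exact adjusted p = 0.0302). Against random lists matched on gene length and spacing, the OTX1 calls for DNA replication (permutation adjusted p = 0.0600) and late differentiation (0.145) were lost and the other calls in this paragraph kept. Neighbouring genes of a list can count the same region at this distance, and the matched lists were not drawn to hold such neighbours. Without peaks in a high local background, the E2F1 excess of the endoderm and the organizer and axis genes as 1 group was lost (odds ratio 1.19, Fisher's exact p = 0.476). This removal also took out tall peaks. It was not run within 5 kb for the other lists or for OTX1, so whether those calls would stay is unknown.

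E2F1 and OTX1 regions overlapped far more often than randomly placed regions, and mostly away from gene ends. The factors were precipitated from separate samples, so the overlap is one of called regions and does not show both factors on the same DNA. Of the 13216 E2F1 regions, 2987 (22.6%) overlapped an OTX1 region, 17.3 times the 1.31% of randomly placed regions (permutation p = 0.001, the smallest possible) and 13.4 times the 1.68% of placements that kept gene-end regions at gene ends. In the other direction 3019 OTX1 regions (17.0%) overlapped an E2F1 region. The overlap took in 35.5% of the 6418 E2F1 regions away from gene ends (chance 1.15%) and 10.4% of the 6798 at gene ends (chance 2.19%). Of the few OTX1 regions at gene ends, 47.9% overlapped an E2F1 region (chance 10.2%), against 14.2% of those elsewhere (chance 0.467%). At shared places the summits lay a median of 91 bp apart, and 54.7% lay within 100 bp of each other.

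**Figure D3:**
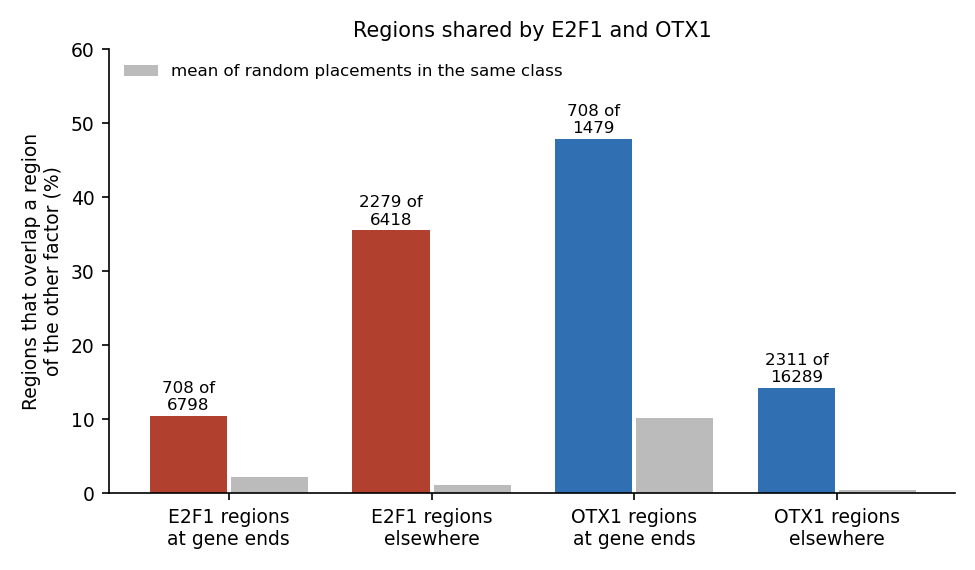
Percent of the reproducible regions of E2F1 (red) and OTX1 (blue), at gene ends and elsewhere, that overlapped a region of the other factor, with grey bars for the mean of 1000 random placements within the class. All 4 observed bars stand above the grey ones, from 10.4% against 2.19% to 47.9% against 10.2%.

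The shared regions lay between the other classes in their position. Among the 8492 E2F1-only regions 61.5% were at gene ends, among the 2987 shared ones 23.7%, and among the 12682 OTX1-only regions 4.75%. The odds ratio of lying at a gene end was 5.14 for E2F1-only against shared regions (95% interval 4.67 to 5.65, Fisher's exact p = 3.49e-286) and 6.22 for shared against OTX1-only regions (5.53 to 7.0, p = 5.61e-196). At shared places the folds of the factors had Spearman correlations between 0.0830 and 0.129 over the 4 pairs of lists. At the level of genes, 952 had regions of both factors at an end, against 545 for independent lists (odds ratio 3.19, 95% interval 2.87 to 3.54, Fisher's exact p = 3.40e-105). Of the genes with an OTX1 region there, 61.0% also had an E2F1 region. When summits had to lie within 100 bp of each other both between replicates and between factors, 10.4% of the E2F1 regions were shared, and with lists of equal size 15.9%, both above every placement.

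Shared regions within 5 kb were frequent in several developmental lists. They lay at 13 of 35 organizer and axis genes (37.1% against 6.79% of other genes, odds ratio 8.11, Fisher's exact adjusted p = 1.74e-06), 13 of 38 maternal factors (7.14, 3.28e-06) and 16 of 48 endoderm and mesendoderm genes (6.88, 5.26e-07). The next were 14 of 43 ectoderm genes (odds ratio 6.63, exact adjusted p = 2.81e-06), 11 of 36 hox genes (6.03, 6.45e-05) and 18 of 98 signalling genes (3.09, 0.00034). Neighbouring genes can count the same region, as hoxa4 with hoxa5, hoxb7 with hoxb8 and mix1 with bix1.2 did. The members of such lists are therefore not independent observations. The lists for core transcription (8 of 89, exact adjusted p = 0.529), ribosomal proteins (8 of 78, 0.366), histones (3 of 28, 0.561), DNA replication (9 of 64, 0.0758) and the cell cycle (10 of 72, 0.064) did not pass. Late differentiation genes had fewer (2 of 137, odds ratio 0.201, exact adjusted p = 0.0159). E2F1-only regions within 5 kb were instead more frequent at DNA replication (48 of 64, odds ratio 6.09, exact adjusted p = 3.90e-10), cell cycle (52 of 72, 5.28, 3.90e-10) and ribosomal protein genes (48 of 78, 3.25, 2.08e-06). The same held for maternal factor (23 of 38, odds ratio 3.1, exact adjusted p = 0.00209), core transcription (52 of 89, 2.85, 4.81e-06) and histone genes (16 of 28, 2.70, 0.0215). OTX1-only regions were more frequent at organizer and axis (14 of 35, 4.11, 0.000412) and endoderm and mesendoderm genes (13 of 48, 2.29, 0.0426).

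The strongest shared regions at gene ends lay at letm2, a relative of a mitochondrial carrier gene (E2F1 folds of 14.9 and 14.2, OTX1 folds of 10.4 and 12.8), tctn3, a gene of the primary cilium (14.4 and 14.0; 9.21 and 10.6), the nucleoside diphosphate kinase nme3 (9.81 and 13.0; 9.43 and 10.4). Next was the common end of ilk, integrin-linked kinase, and rrp8 (12.3 and 10.2; 8.5 and 11.0). Lower in rank were ccdc9 (13.2 and 11.8; 7.52 and 9.42), ube2z, a ubiquitin-conjugating enzyme (9.39 and 9.78; 12.0 and 14.8), mix1, prkar1a, a regulatory subunit of protein kinase A (12.9 and 11.9; 7.34 and 8.07), and gpatch2 (12.0 and 13.2; 6.95 and 8.07). At mix1, an early zygotic homeobox gene of the mesendoderm (chromosome 5, 8057280 to 8060597), both factors peaked at 1 end (E2F1 8060359 to 8060858, folds of 9.51 and 9.35; OTX1 8060399 to 8060862, folds of 10.1 and 10.5) and again within 371 bp of the other.

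Other genes fixed in advance showed each pattern. No pou5f3 gene, the frog relatives of the pluripotency factor Oct4, had a region at its end, but a shared region lay between pou5f3.3 and pou5f3.2 (chromosome 8; E2F1 3284558 to 3284926, folds of 6.75 and 5.69; OTX1 3284575 to 3284950, folds of 8.33 and 7.48), and an E2F1-only region between pou5f3.2 and pou5f3.1 (3294612 to 3295060, folds of 7.97 and 8.15). At nodal on chromosome 7, a signal of mesendoderm induction, both factors sat inside the gene (E2F1 42146203 to 42146575, folds of 4.90 and 6.53; OTX1 42145907 to 42146590, folds of 7.91 and 9.52). On chromosome 3 a shared region lay 3594 bp from nodal6 (E2F1 4.93 and 5.79; OTX1 4.60 and 6.80), nodal1 carried E2F1 872 bp inside its end (5.94 and 7.71), and nodal5, nodal2 and nodal3.1 had no reproducible region at an end. The siamois genes sia1 and sia2 had none at an end either; near sia2 an OTX1 region shared with E2F1 had its summit 4536 bp away (OTX1 4.96 and 5.51) and an E2F1 region 3213 bp away (6.08 and 7.25).

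The genes of the OTX family and sox3 had E2F1 regions at or near an end. At otx1 no region lay at an end; an E2F1 region inside the gene had folds of 5.61 and 6.63 over a local background of 14.2 and 14.8 fragments, and a shared region lay 1945 bp beyond the end (OTX1 3.89 and 4.93). Its relative otx2 had an E2F1 region 1154 bp (4.50 and 4.44) and an OTX1 region 2718 bp from an end (4.91 and 3.4). Sox3, a neural and pluripotency factor, had E2F1 at its end with folds of 4.1 and 4.36 over a background of 9.0 and 10.9 fragments, and OTX1 peaks 5362 and 5239 bp away with folds of 8.43 and 7.96. At gsc an E2F1 peak stood at the OTX1 region in replicate 1 alone (4.40).

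**Figure D4:**
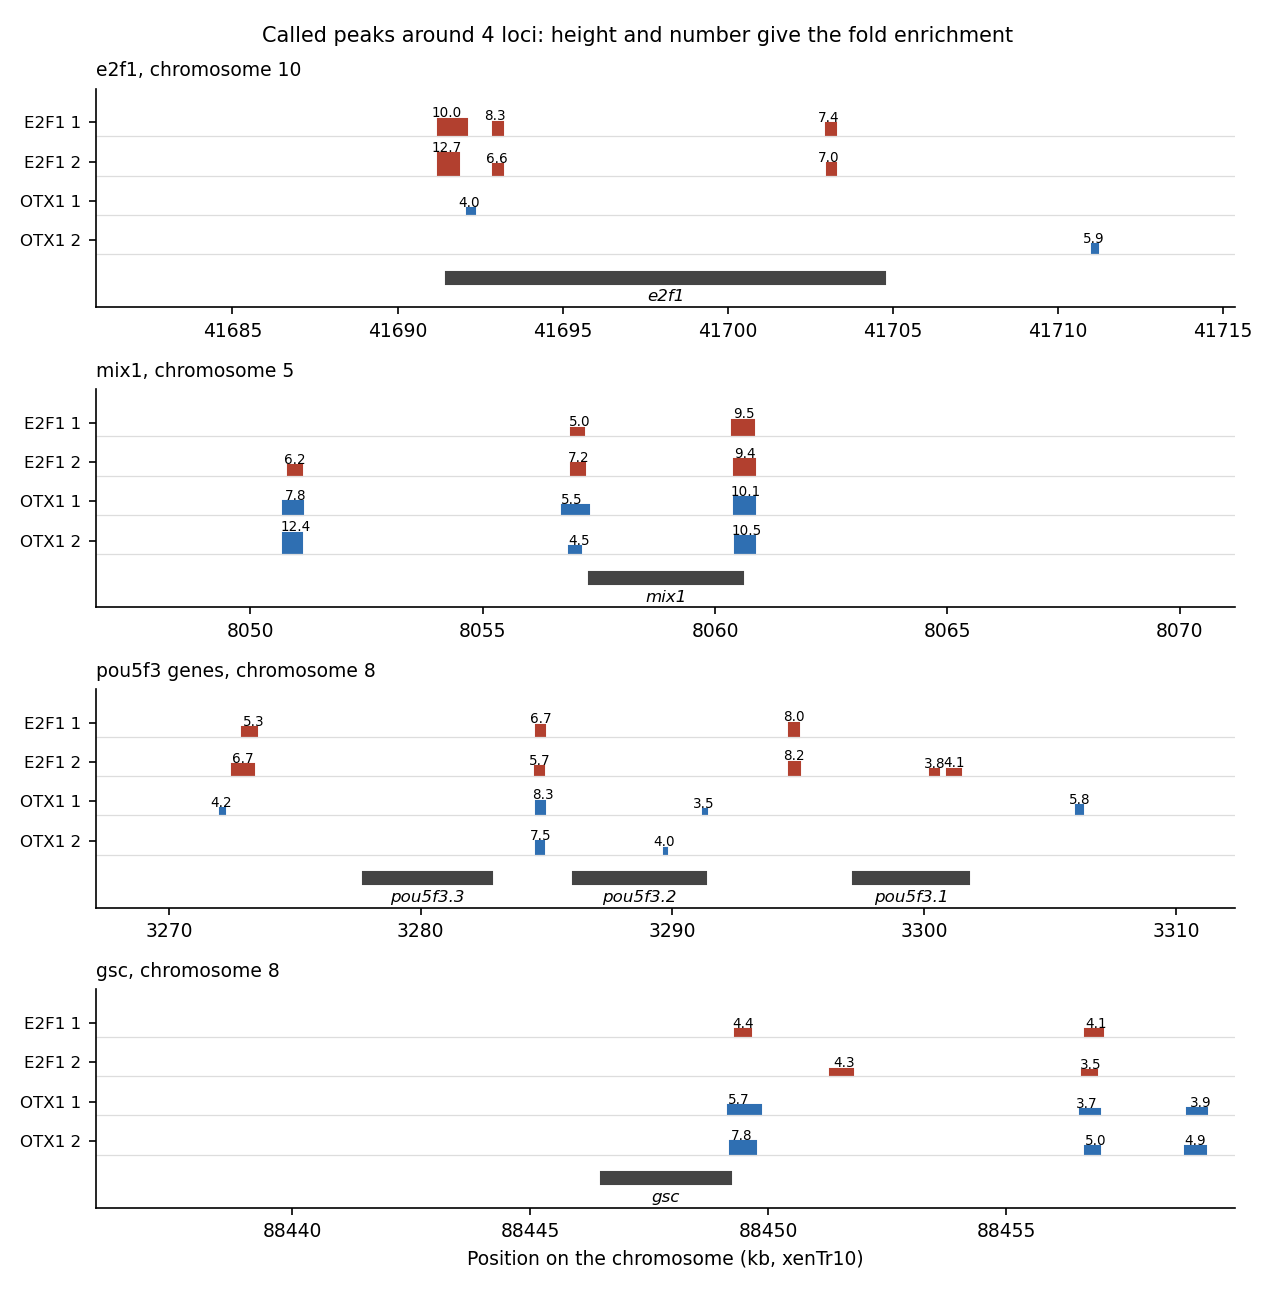
Called peaks of the 4 lists within 10 kb of e2f1, mix1, the pou5f3 genes and gsc; the horizontal axis is the position in kb on xenTr10, the height of a block and the number above it give the authors' fold of that peak within its own list, and dark bars are the named genes (other genes are not drawn). E2f1 had its highest E2F1 peaks at an end, 10 and 12.7, mix1 had peaks of all 4 lists at both ends, and gsc had OTX1 peaks of 5.69 and 7.76 at an end.

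Genes with only 1 of the factors at an end differed between the lists. Of the organizer and axis genes, 7 had E2F1 alone, 6 OTX1 alone and 3 both, while other genes had 6637 with E2F1 alone and 603 with OTX1 alone (odds ratio 0.106, 95% interval 0.0366 to 0.301, Fisher's exact adjusted p = 0.00421 over 12 lists). Gsc, with OTX1 alone, and ventx3.1 and ventx2.2 lost their OTX1 regions without peaks in a high local background, where this test was not rerun. Late differentiation genes had E2F1 alone at 9 and OTX1 alone at 5 (odds ratio 0.164, 0.0549 to 0.451, exact adjusted p = 0.0260). No other list passed this test, including endoderm and mesendoderm (6 and 3, exact adjusted p = 0.0987), core transcription (63 and 1, 0.0987) and the cell cycle (50 and 0, 0.0797).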

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

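The test of high local background on shared regions and on the 5 kb lists was set before its result was seen; the other tests below were chosen after the results were seen. A list of genes was picked out where the balance of the factors at gene ends differed between its members and other genes. The organizer and axis genes had an odds ratio of 0.106 for E2F1 alone against OTX1 alone (7 and 6 genes), and the late differentiation genes 0.164 (9 and 5 genes). Both rest on few genes, and neither test was rerun without peaks in a high local background.

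Genes other than protein-coding ones were outside the comparisons, and several classes had E2F1 regions within 1 kb of an end more often than 1000 placements gave on average (adjusted permutation p of at most 0.008). Only regions away from protein-coding gene ends were counted. The classes were lncRNA genes (5.23% of 2350 against 1.54% by chance), misc_RNA genes (23.8% of 42 against 1.78%), transcribed pseudogenes (19% of 21 against 1.66%), other pseudogenes (3.65% of 548 against 1.30%) and tRNA genes (2.45% of 2366 against 0.907%). No class passed for OTX1 after adjustment over the 20 tests.

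The overlap of E2F1 and OTX1 regions, 22.6% of E2F1 regions, was weighed against 3 technical explanations. The first was sequence with a high local background in every library. Without peaks above 3 times the lowest background, 32.4% of the E2F1 regions away from gene ends were still shared, against 1.04% by chance. Peaks above that limit, 17.3% and 15.7% for E2F1 and 4.59% and 5.26% for OTX1, therefore do not account for the whole overlap. The background may include the precipitated signal itself, so the filter cannot single out nonspecific sequence. Such sequence below the limit stays open. Open chromatin at gene ends recovered by either antibody concerns gene ends alone, so regions away from them cannot test it. Of those regions 35.5% were shared, above the 1.56% of the highest placement, so gene ends do not account for the whole overlap. For the 47.9% of OTX1 regions shared at gene ends (highest placement 12.4%) the question stays open, because no library without a tagged factor was used here. A common nonspecific signal that sets peak height stays open: rank correlations of fold between the factors were at most 0.140 away from gene ends, against 0.649 and 0.691 for replicates of E2F1 and OTX1, but those replicates differ perhaps only technically. Joint binding by both factors, open chromatin elsewhere and the excess of injected protein were not tested.

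The excess of endoderm and of organizer and axis genes with an E2F1 region within 5 kb, 57 of 82 (69.5% against 43.5% of other genes, odds ratio 2.96), was weighed next. Gene length and spacing alone were argued against: the larger permutation adjusted p of these lists against matched random lists was 0.0018. The matched lists were not drawn to hold neighbours that count the same region, as mix1 and bix1.2 do. Clustering of the list members therefore stays open as a source of the excess. Regions shared with OTX1 could carry the excess. Of the 57 genes, 29 (50.9%) had a shared region against 15.5% of other genes with an E2F1 region (odds ratio 5.66, 95% interval 3.37 to 9.50). E2F1-only regions lay at 37.5% of the endoderm (odds ratio 1.21, Fisher's exact adjusted p = 0.648) and 34.3% of the organizer and axis genes (1.05, 0.910). High shares with a shared region were not particular to these lists: ectoderm had 43.8%, hox 44.0%, maternal 43.3% and signalling genes 35.3%. Peaks in a high local background could carry the excess as well, since without them the odds ratio was 1.19 (0.762 to 1.88). Within each list the background rose with the summit pileup (Spearman 0.785 and 0.803 for E2F1), so this removal also takes out tall peaks, and these explanations do not exclude each other.

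The highest folds of the OTX1 lists lay at 2 sites on chromosome 9, and both were also called in the E2F1 lists. Site 1 (55840980 to 55841267 in OTX1 replicate 1) had folds of 46.2 and 45.8 for OTX1 and 19.8 and 22.0 for E2F1 and lay 22.1 kb from the nearest gene end, and site 2 (55707093 to 55707614) had 43.1 and 46.6 and 18.6 and 19.9 and lay 156 kb from one. A pile of reads from near-identical copies was weighed for both. At site 1 the summit pileup over the lowest background of each list differed by 1.75 times between the highest and the lowest of the 4 lists. The local background over the lowest differed more there, with 12.8 and 14.4 for E2F1 and 3.49 and 3.94 for OTX1. The lowest background also depends on fragment length, so equal copies stay open for site 1. At site 2 the summit pileup over the lowest background differed by 4.08 times. The pileups were 796 and 973 fragments for E2F1 and 304 and 311 for OTX1, which argues against equal copies as the whole cause there. No biological explanation was tested for either site.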

How the results depend on the processing

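No paired analysis was possible because the results come from joined peak lists, without a fit that could hold a replicate block, and the labels tie no replicate of E2F1 to one of OTX1. E2F1 lists overlapped OTX1 lists of the same number in 27.9% and 26.7% of peaks and of the other number in 27.7% and 27.1%. Over all alternatives run, the share of E2F1 regions shared with OTX1 (10.4% to 27.9%), the shares at gene ends (E2F1 41.0% to 63.1%, OTX1 5.48% to 26.0%) and the odds ratio of genes with both factors (2.18 to 3.96) kept their direction and stayed past the threshold, and 9408 to 13201 E2F1 regions were reproducible. Counts that moved by over 1.5 times were the reproducible OTX1 regions with equal list sizes (10902) and the genes with OTX1 at an end: 829 with equal list sizes, 954 at a −log10 q of at least 5, 1027 with summits within 100 bp, 4791 in a 5 kb window, 9050 with gene bodies and 10 kb, and 2563 to 2735 when a replicate was left out, where 1 list suffices by construction. Genes with E2F1 rose to 11642 with gene bodies and 10 kb. Of the 24 tests of lists and factors, 9 passed. In other settings 19 did in a 5 kb window, 19 with gene bodies and 10 kb, and 5 without peaks in a high local background, where the E2F1 odds ratio of the maternal factors reversed to 0.354 (exact adjusted p = 0.0852). Wider windows count more regions by construction; the cause of the other changes was not tested. Common thresholds, gene bodies, matched lists and the background filter were chosen after the data were seen. Of 137 named genes, 64 lost a gene-end region without peaks in a high local background, 31 with summits within 100 bp and 27 in a 500 bp window. In every list the peaks removed by the background filter had a higher median pileup than the others. Motif tests, GC matching and ends of single transcripts were not run, since no sequence or transcripts were used. Median pileups of 15 to 16 fragments limit weak peaks: a gene without a called region was not detected at this depth.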

Other observations

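All tests in this part were chosen after the data were seen. Families of genes that share the start of their symbol were also compared, some of which overlap the fixed lists. Of 119 such families with at least 15 members, 41 had E2F1 at gene ends more often than other genes and 9 less often (Fisher's exact test, Benjamini-Hochberg adjusted), while for OTX1 none passed and 8 had an unadjusted p under 0.05. Translation initiation factors (eif) had E2F1 at 43 of 49 genes (87.8%, exact adjusted p = 2.89e-12), nuclear pore genes (nup) at 18 of 20 (90.0%, 7.27e-06), centrosomal genes (cep) at 26 of 34 (76.5%, 1.55e-05), mitochondrial ribosomal genes (mrpl) at 33 of 47 (70.2%, 1.55e-05) and zinc finger genes (znf) at 84 of 145 (57.9%, 5.89e-07). Olfactory receptor genes (or) had it at 0 of 35 (exact adjusted p = 5.96e-06) and transmembrane protease genes (tmprss) at 0 of 19 (0.00181).

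The highest local background of the peaks near a gene differed between gene lists. It was taken among peaks of reproducible regions within 5 kb of an end, over the lowest of the peak list. The values of both peak lists of a factor were averaged. Genes with more peaks nearby can have higher values by construction, and neighbouring genes can share a peak. Around E2F1 regions the median of this value over all genes with such a region was 2.27 times the lowest of the peak list. The median was 4.90 times for ectoderm genes (32 genes, adjusted permutation p = 0.0006) and 3.49 for organizer and axis genes (22 genes, 0.00175), while for endoderm genes it was 2.67 (35 genes, 0.125). Histones (5.22), hox genes (4.54) and maternal factors (4.40) were also above it (adjusted permutation p = 0.0006 each, from the smallest p that 10000 lists can give), and so were cell cycle (2.97, 0.00107) and DNA replication genes (2.78, 0.0056). Around OTX1 regions the median was 4.23 for ectoderm, 3.4 for hox, 2.98 for organizer and axis and 2.67 for endoderm genes against 1.68 (adjusted permutation p = 0.0006 each) and 2.17 for signalling genes (0.00175). DNA replication (1.78, adjusted permutation p = 0.634) and cell cycle genes (1.5, 0.422) did not pass there. By gene, the highest E2F1 values were at galnt7 and hmgb2 (16.2), set (14.7), ptma (13.8) and hmgn2 (13.4), with otx1 at 12.2, and the highest OTX1 values at fgf8 (7.85), cxcl12 (7.2), spint2 (6.30), pim3 (6.13) and irx3 (5.97). These genes were picked by their values. What lies behind such values was not tested.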
